A study of Mus musculus with 6 samples.

How the data were processed

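RNA was measured by bulk RNA sequencing in 6 libraries from MC3T3-E1 cells, a line of bone-forming precursor cells from the mouse calvaria, the roof of the skull. Per the labels' protocols, cells were plated for 24 h, transfected by lipofection with a plasmid carrying wild-type or mutant Casr and harvested 48 h after transfection. Per the same labels, 1.3 µg of total RNA entered each library, which was made with an mRNA kit. The titles put 3 libraries in the wild-type group (CaSRwt) and 3 in the mutant group (CaSRmut) and call the libraries of a group biological repetitions. The genotype labels of the 3 CaSRmut libraries name the same amino acid change at 3 different residue numbers, while their titles name 1 plasmid, so they were treated as 1 group. The sources used here do not say whether the repetitions came from separate passages or days, so p-values measure the spread between these cultures. No untransfected or empty-vector culture was analysed here.

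The deposited values were a table of whole-number read counts per gene, with 1 column per library and no normalization, and a table of FPKM (fragments per kilobase of gene, scaled to library size). Counts divided by gene length and by the deposited FPKM gave 1 constant per library, so the authors made the FPKM values from these counts and the listed gene lengths. That constant differed from the column total by -1.70% to 1.43%. It lay below the total in the libraries whose TMM normalization factor was below 1 and above it in the others. The FPKM values were therefore not scaled by the column total alone. The aligner, the counter, the annotation release and the use of strand are not given in the sources used here. Genome build GRCm38 (mm10) is named per the submitters' processing notes. Gene starts in the deposited count table matched those of GENCODE M21 on GRCm38 for 1485 of 52073 shared gene identifiers (2.85%), so the coordinates in the table were not used. Positions given in the text are those of GENCODE M21 on GRCm38, looked up by gene identifier. Strand being unknown, reads of overlapping or antisense genes cannot be told apart. The species of the inserted coding sequence is not given in the sources used here, and Casr counts are the reads assigned to the mouse gene. All 6 columns of libraries were used, and 0 columns belonged to other samples.

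Total counts were 34180786, 35462227 and 34396661 in CaSRwt and 34527996, 38764076 and 35659042 in CaSRmut. Of 56748 genes listed, 32112 had a count in at least 1 library. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation and glmQLFTest, two-sided) on the deposited counts, with TMM normalization and the default expression filter of edgeR by group, which kept 16878 genes. P-values were adjusted by the Benjamini-Hochberg method over the genes kept, and the threshold was an adjusted p of 0.05. A second count required a change of at least 2-fold as well. CPM, counts as a rate per library, used TMM-scaled library sizes and is given as mean ± SD over 3 libraries per group. Log2 fold changes are CaSRmut minus CaSRwt. Their standard errors were approximated as the absolute log2 fold change over the square root of the F statistic. The 95% intervals used the total degrees of freedom of the moderated test, prior and residual together. A gene with 0 counts was given an upper limit of 3 counts per library, which is 0.0774 to 0.0878 CPM. Such limits and binomial intervals cover counting error only, since the counts have no molecular identifiers.

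Before the data were examined, 35 gene lists, the tests, the alternatives and the genes to be named were fixed. The lists covered bone cells and their neighbours, signalling, stress and metabolic programs, and markers of other cell types, and 25 of 646 distinct genes stood in more than 1 list. The 32 lists with at least 5 members tested were compared with the other genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. The same test with an estimated correlation, and fry, were run beside it. By the naming rule, Casr and 7 osteoblast genes were always named, then genes past the threshold, and, since no protein-coding gene passed in a direction, the 5 protein-coding genes per direction with the smallest p whose groups did not overlap and whose mean CPM was at least 1. Up to 4 members with the smallest p were named per list. Shares of counts were compared by exact two-sided permutation tests, whose smallest p is 0.1 with 3 libraries against 3.

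The procedure was tested on simulated counts for 16459 genes drawn from the means and library sizes of these libraries, with 200 genes changed. Among changed genes with a mean CPM of at least 10, it recovered 15 of 22 changed by 1.25-fold, 27 of 28 changed by 1.5-fold, 22 of 22 changed by 2-fold and 18 of 20 changed by 3-fold. Of 129 calls, 11 were false. Over all abundances, it recovered 16, 32, 29 and 41 of 50 genes changed by 1.25-, 1.5-, 2- and 3-fold. The Benjamini-Hochberg adjustment is less strict where many genes change, as here with 200. These rates therefore overstate the recovery to be expected where few genes change. A simulated list of 30 genes shifted by 0.1 on the log2 scale gave a camera p of 8.1e-08, and an unchanged list gave 0.819. Simulated genes were drawn independently of each other. The correlation estimated in the lists that camera called was 0.143 to 0.323, so the simulation does not test camera for such lists.

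The alternatives were other normalizations (RLE, upper quartile, library size only), no filter and a stricter filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, a correction for gene length with and without that block, Casr or the mitochondrially encoded genes left out, protein-coding genes only, limma-trend on log2 FPKM with a pseudocount of 1 or 0.1 and with or without a filter at a mean FPKM of 0.5, and each library left out in turn. On the FPKM scale a fold change is that of log2(FPKM + pseudocount) and understates low genes. Within groups, the Pearson correlation of log2 CPM across genes was 0.988 to 0.990, and counts of every pair of libraries differed by more than sampling noise (chi-square per degree of freedom 4.85 to 9.83), so no library was counted as a repeat of another. Figures were drawn with matplotlib 3.10.9.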

Results

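Gene expression was measured in MC3T3-E1 cells 48 h after transfection with a plasmid carrying either wild-type or mutant Casr. Casr encodes the calcium-sensing receptor, a G protein-coupled receptor that responds to extracellular calcium. MC3T3-E1 is a mouse calvarial line used as a model of osteoblast precursors. The series title ties activation of this receptor to overgrowth of the mandible, and the single comparison of the design asks how the transcriptome differs between cells given the mutant and cells given the wild-type receptor. Each group held 3 libraries. Total counts per library ran from 34180786 to 38764076, and between 24577 and 25390 genes had at least 1 read in a library. Both groups received Casr, so neither is an untransfected background.

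Casr was the most abundant gene in both groups, with a mean of 1.87% of all counts over the 6 libraries. Its gene (ENSMUSG00000051980) lies on the minus strand of chromosome 16 at 36493696 to 36562141 in GRCm38. Counts were 701156, 752778 and 626500 in the CaSRwt libraries and 656649, 681975 and 558917 in the CaSRmut libraries. The level was 19918 ± 1637 CPM in CaSRwt and 17540 ± 1893 CPM in CaSRmut (SD, n = 3 each), or 2.00% ± 0.157 and 1.74% ± 0.168 of counts. The log2 fold change was -0.18 (SE 0.10, 95% interval -0.42 to 0.05) with an adjusted p of 0.932 in edgeR, and the exact two-sided permutation test of log2 CPM gave p = 0.2, where 0.1 is the smallest possible. The CPM of the libraries of the groups overlapped. Without CaSRmut replicate 3 the log2 fold change was -0.10. With the replicate number as a block it was -0.19 (edgeR adjusted p = 0.000558), but the numbers did not meet the rule set for pairing. Because both groups carry the transgene, this level checks its amount and not the mutation.

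Genes with a mean CPM of at least 10 stood at closely similar levels in the cultures given mutant and wild-type receptor. Of 16878 genes tested with edgeR, 1 passed an adjusted p of 0.05, and it was higher in CaSRmut. That gene, H3f3c (ENSMUSG00000082029), is annotated as a processed pseudogene of the histone H3.3 family on chromosome 2, minus strand, 119665626 to 119666036 in GRCm38. It had 24, 16 and 30 counts in the CaSRwt libraries and 83, 96 and 76 in the CaSRmut libraries, or 0.673 ± 0.210 against 2.35 ± 0.205 CPM (SD, n = 3 each). Its log2 fold change was 1.80 (SE 0.30, 95% interval 1.20 to 2.41, adjusted p = 0.0124 in edgeR), and H3f3c was also the only gene past both the threshold and 2-fold. Since 73.8% of the 50-base windows in its transcript also occur in transcripts of other genes, H3f3a foremost, its count is uncertain. The call was lost without CaSRwt replicate 2 (adjusted p = 0.137) and without CaSRmut replicate 2 (0.182), while limma-voom on the same genes gave 0 calls and 928 genes at an unadjusted p under 0.05.

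The precision behind that count was high for expressed genes. Of 8962 genes with a mean CPM of at least 10, the 95% interval of the fold change lay within 2-fold for 8918 (99.5%) and within 1.5-fold for 8874 (99.0%). Of 13026 genes with a mean CPM of at least 1, 12546 (96.3%) had an interval within 2-fold. Over all 16878 genes tested this was 13055 (77.3%), and 10865 (64.4%) lay within 1.5-fold, so for the less abundant genes larger differences stay open. These intervals are for whole cultures. The share of cells that took up plasmid was not measured here, so larger differences within those cells stay open as well. At an unadjusted p under 0.05 there were 911 genes, where 843.9 would be expected with no difference. Among protein-coding genes tested alone, 0 of 12539 passed in edgeR and 661 had an unadjusted p under 0.05, while DESeq2 on all genes called H3f3c and 1 protein-coding gene, Ly6e. Without CaSRmut replicate 3 the edgeR count over all genes was 11, and without CaSRwt replicate 1, CaSRwt replicate 3 or CaSRmut replicate 1 it was 5, 5 and 4.

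**Figure D1:**
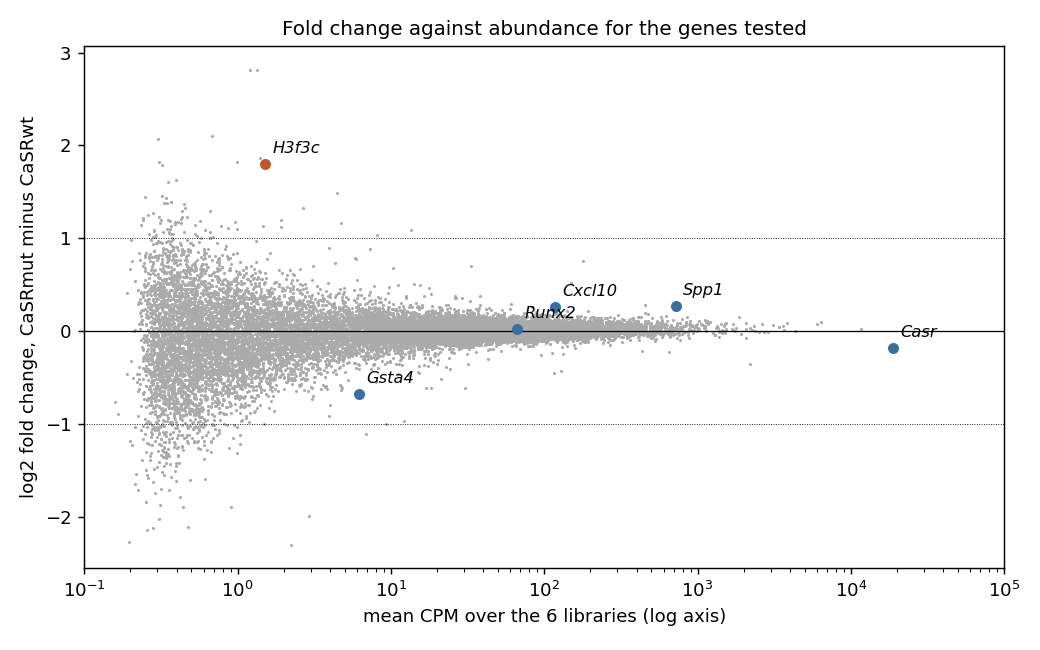
Log2 fold change (CaSRmut minus CaSRwt) of each of the 16878 genes tested, against its mean CPM over the 6 libraries on a log axis, with dotted lines at 2-fold. H3f3c (orange) is the gene past the threshold at a log2 fold change of 1.80, while Casr, the most abundant gene, lies at -0.18 and the points close in on 0 as abundance rises.

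The protein-coding genes nearest to the threshold included members of the interferon program among those with higher values. None of the 10 named here passed in edgeR over all genes. Cxcl10, an interferon-induced chemokine, stood at 106 ± 6.54 CPM in CaSRwt and 128 ± 8.79 CPM in CaSRmut, a log2 difference of 0.26 (SE 0.06, adjusted p = 0.135). Dhx58, an interferon-induced RNA helicase, went from 54.7 ± 1.39 to 64.5 ± 1.67 CPM (0.24, adjusted p = 0.217), and Ly6e, a GPI-anchored protein also induced by interferon, from 421 ± 10.9 to 482 ± 13.1 CPM (0.19, adjusted p = 0.208). Filip1l had a log2 difference of 0.35 and Id3, an inhibitor of DNA binding that responds to BMP signalling, 0.22, both with an adjusted p of 0.223. The lower values were those of Eid3 (-0.45, adjusted p = 0.135), the glutathione transferase gene Gsta4 (-0.68, 0.173), Slc35f1 (-0.79, 0.208), Rragd (-0.46, 0.234), which encodes a Rag GTPase, and the protease inhibitor gene Slpi (-0.37, 0.378). Gsta4 stood at 7.64 ± 1.53 CPM in CaSRwt and 4.78 ± 0.197 CPM in CaSRmut. Cxcl10, Filip1l and Eid3 overlap Art3, Cmss1 and Txnrd1 in the annotation, and Dhx58 overlaps Dhx58os, so their counts are uncertain. The same holds for Slc35f1 (Gm47624 among others), Rragd (Gm11943) and Slpi (Mir7678), and for Casr (Gm25902), Runx2 (Supt3 among others) and Spp1 (Gm42793). Cxcl10 passed without CaSRwt replicate 1 (adjusted p = 0.0317) and without CaSRmut replicate 3 (0.0155), and Gsta4 passed without CaSRwt replicate 3 (0.0363). With no filter, Cxcl10 (0.00312), Ly6e (0.0320), Filip1l (0.0115), Id3 (0.0168), Eid3 (0.0113), Gsta4 (0.0113) and Slc35f1 (0.0275) passed in edgeR, and Ly6e also in DESeq2 (0.0257), so the side of the threshold on which these genes lay depended on the procedure.

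No osteoblast gene passed over the 16878 genes tested. Runx2, the master transcription factor of the lineage, was at 65.7 ± 0.524 CPM in CaSRwt and 67.0 ± 2.80 CPM in CaSRmut (log2 difference 0.03, 95% interval -0.09 to 0.14). Col1a1, which encodes the main collagen of bone, was at 546 ± 39.2 and 607 ± 24.1 CPM (0.15, SE 0.05, interval 0.05 to 0.25), and Spp1, the gene of the matrix protein osteopontin, at 655 ± 54.3 and 788 ± 83.7 CPM (0.27, SE 0.09, interval 0.06 to 0.48). Their adjusted p values over all genes were 0.741 and 0.899 in edgeR, although Spp1 passed without CaSRmut replicate 3 (0.0155) and with no filter (5.05e-05). With no filter its log2 fold change was still 0.27, so the smaller p did not come from a larger difference. The variance estimates of that fit also drew on genes that the main filter removes. The groups of Spp1 overlapped, with 712 CPM in CaSRwt replicate 1 and 703 CPM in CaSRmut replicate 3. Sparc (osteonectin) had a log2 difference of 0.15 and Col1a2 of 0.15, each with an adjusted p of 0.741. The other osteoblast genes that were always named had few or no counts. Sp7 stood at 0.212 ± 0.0720 and 0.271 ± 0.184 CPM (log2 difference 0.37, adjusted p = 0.984), Alpl at 0.298 ± 0.149 and 0.334 ± 0.206 CPM and Bglap, the gene of osteocalcin, at 0.171 ± 0.0941 and 0.0988 ± 0.0720 CPM. The last 2 had too few counts to be tested. Ibsp had 0 counts in all 6 libraries, which allows up to 0.0774 to 0.0878 CPM per library, so a difference was not detectable at this depth. In the list of osteoblast differentiation and bone matrix genes, 10 of 14 members tested were higher, with a median log2 difference of 0.11, which was 0.0639 without CaSRwt replicate 2 and 0.186 without CaSRmut replicate 3. The list did not pass (camera adjusted p = 0.108, 0.834 with an estimated correlation), though it did without CaSRmut replicate 3 (0.0360) and under the stricter filter (0.0436). Of its members, 0 passed over all genes and 3 passed when adjusted over the list alone, namely Sparc, Col1a1 and Col1a2.

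**Figure D2:**
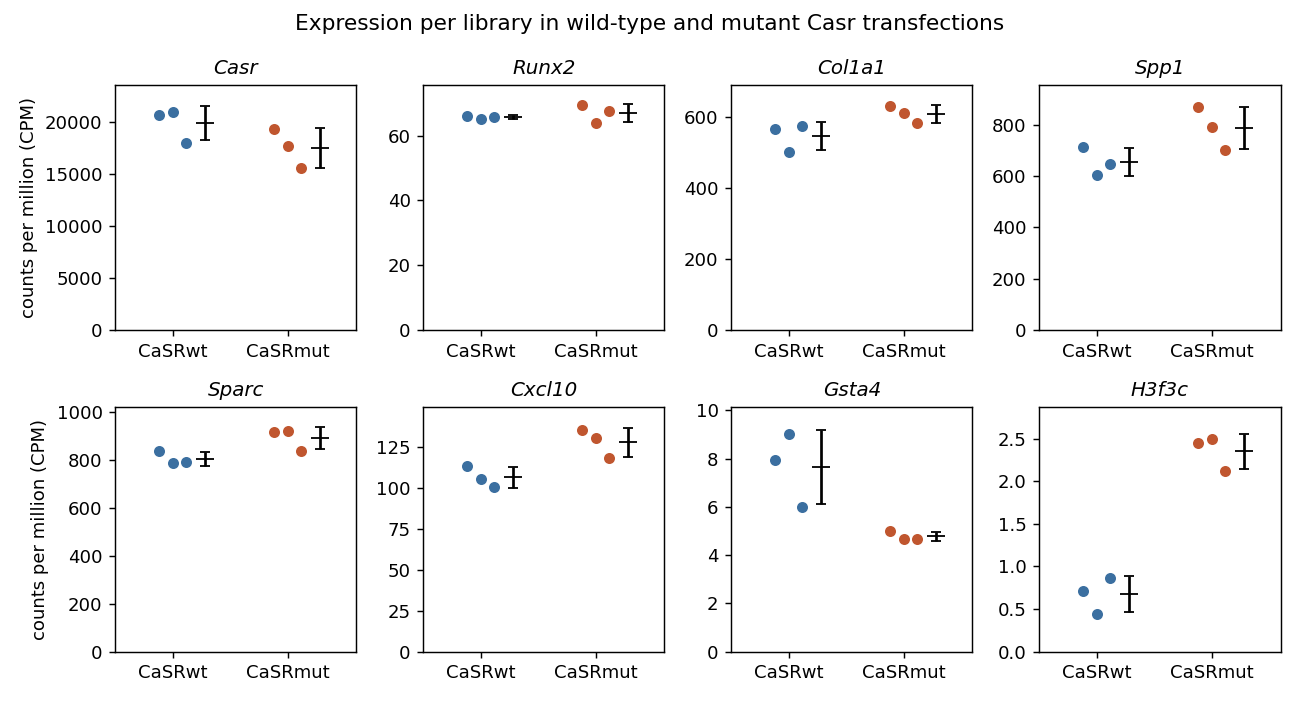
CPM of 8 genes in each of the 6 libraries (points, CaSRwt blue and CaSRmut orange, each axis starting at 0), with the mean and SD of each group (n = 3) in black. The CaSRmut libraries hold 2.35 ± 0.205 CPM of H3f3c against 0.673 ± 0.210 in CaSRwt, while the groups of Casr and Runx2 overlap.

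Among the 32 gene lists tested, 5 were shifted upwards and 1 downwards in CaSRmut by camera with its preset correlation, all by small amounts. The interferon response list had the smallest camera p: 30 of 34 members were higher, by a median of 0.09 on the log2 scale (6.32%), with an adjusted p of 2.27e-06, which became 0.834 with an estimated correlation. No member passed over all genes and 8 passed when adjusted over the list alone (Cxcl10, Dhx58, Gbp2, Ifi35, Gbp7, Oas2, Irf9 and Ifit1), all higher in CaSRmut. Gbp2 stood at 41.7 ± 1.15 and 48.8 ± 4.49 CPM and Ifi35 at 95.4 ± 2.65 and 108 ± 9.16 CPM. In the list of extracellular matrix and remodelling genes, 20 of 23 members were higher, by a median of 0.10 (7.28%, adjusted p = 0.000536, and 0.834 with an estimated correlation). Without CaSRmut replicate 1 this median was 0.0529. Here 0 members passed over all genes and 4 adjusted over the list alone: Col3a1 (76.1 ± 3.10 and 90.8 ± 9.60 CPM), Bgn (587 ± 39.9 and 656 ± 14.1 CPM), Timp2 (1752 ± 97.8 and 1950 ± 102 CPM) and Col6a1 (50.7 ± 1.33 and 57.0 ± 1.80 CPM), which encode fibrillar and microfibrillar collagens, a matrix proteoglycan and a metalloproteinase inhibitor. Over all genes, Col3a1 did pass in edgeR with no filter and without CaSRmut replicate 3. Col3a1, Bgn and Timp2 passed with the replicate number as a block.

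The other 4 lists that camera called had medians within 0.1 of 0, and none passed with an estimated correlation, whose adjusted p is given second. Proliferation genes were higher for 23 of 30 members (median 0.06, adjusted p = 0.00761 and 0.834), with the replication licensing genes Mcm6 and Mcm2 at log2 differences of 0.12 and 0.10. Genes of cytosolic ribosomal proteins were higher for 27 of 33 (median 0.04, adjusted p = 0.0134 and 0.952), Rps9 and Rpl13 both by 0.11. The median of the ribosomal protein list was 0.0158 without CaSRmut replicate 3 and 0.0861 without CaSRmut replicate 1, and that of the proliferation list 0.0358 without CaSRmut replicate 1. Targets of YAP-TEAD and SRF, which drive genes of growth and the actin cytoskeleton, were higher for 12 of 14 (median 0.07, adjusted p = 0.0215 and 0.834), with Ccn2 at 0.16 and Srf at 0.14. The oxidative stress list, made of targets of the transcription factor NRF2, was lower for 13 of 15 (median -0.09, adjusted p = 0.0134 and 0.834), with a median of -0.0594 without CaSRwt replicate 2 and -0.138 without CaSRwt replicate 3, and with Gsta4 at -0.68, Slc7a11 at -0.16, Gclm at -0.18 and Prdx1 at -0.11. No member of these 4 lists passed over all genes, and 1 passed when adjusted over the list alone (Gsta4). With an estimated correlation 0 of the 32 lists passed. Fry, which asks whether a list moves one way on balance, called 0 lists (smallest adjusted p = 0.593, 0 lists at an unadjusted p under 0.05), and its test for change in either direction called 3: replication-dependent histones (0.00369), BMP targets (0.0156) and Wnt-beta-catenin targets (0.0156).

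When single libraries were left out, the interferon and extracellular matrix lists passed camera in all 6 fits at the preset correlation, although with all libraries both were lost with an estimated correlation (0.834) and with fry (0.593). Over all 35 lists, leaving out 1 library turned the sign of the median of 18, none of them among the 6 called. The number of lists called was 2 without CaSRwt replicate 2 (those same lists) and 3 without CaSRmut replicate 2 (with proliferation). Proliferation was lost without CaSRwt replicate 2 (adjusted p = 0.185) and CaSRmut replicate 1 (0.239). Ribosomal proteins were lost without replicate 2 of CaSRwt (0.185) and replicates 2 and 3 of CaSRmut (0.171 and 0.486). The YAP-TEAD and SRF list was lost without replicates 1 and 2 of CaSRwt (0.0775 and 0.185) and of CaSRmut (0.262 and 0.233), and the oxidative stress list without replicates 1 and 2 of CaSRwt (0.138 and 0.185) and 2 and 3 of CaSRmut (0.139 and 0.325).

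**Figure D3:**
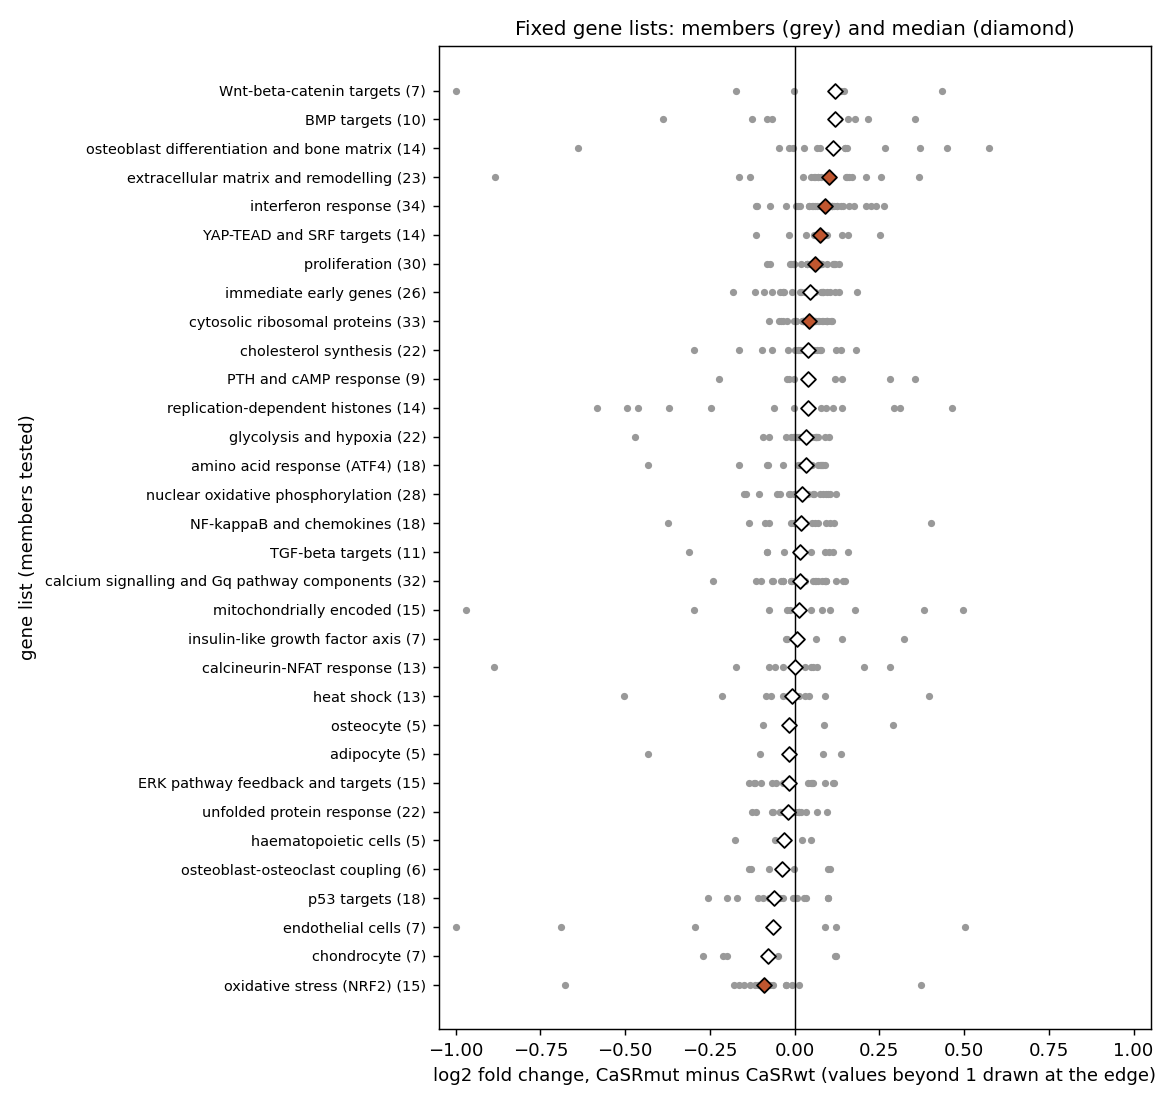
Log2 fold change (CaSRmut minus CaSRwt) of the members tested in each of the 32 gene lists (grey points) and the median of the list (diamond, filled where the camera adjusted p is under 0.05 with the preset correlation). The 2 members beyond 1 on the log2 scale are drawn at the left edge, and the filled medians lie between -0.09 and 0.10.

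The other lists of signalling pathways and their targets did not pass camera with all 6 libraries, and 1 of them, the immediate early genes, did without CaSRmut replicate 3. The BMP and Wnt-beta-catenin lists were called by the fry test for change in either direction (adjusted p = 0.0156 for both). RNA levels of calcium signalling and Gq components do not measure the activity of that pathway. Calcium signalling and Gq components were higher for 20 of 32 members (median 0.01, adjusted p = 0.523), and the list held Plcb4 at 0.12 and the arrestin gene Arrb1 at -0.24. With 1 library left out, the median of this list ran from 0.0014 to 0.0606. Calcineurin-NFAT response genes were higher for 7 of 13 (median 0.00, mean -0.04, adjusted p = 0.917), immediate early genes for 17 of 26 (0.04, 0.422, with a median from 0.0106 to 0.0875 when 1 library was left out), with Myc at 0.13, and ERK feedback genes and targets for 7 of 15 (median -0.02, camera direction upwards, 0.917), with Dusp6 at 0.12 and Dusp4 at -0.12. The PTH and cAMP list was higher for 5 of 9 (0.04, 0.819). Of BMP targets, 6 of 10 were higher (0.12, 0.422, with a median of 0.0666 without CaSRwt replicate 2), and Id3, Atoh8 and Id2 passed when adjusted over the list alone, with log2 differences of 0.22, 0.35 and 0.18. TGF-beta targets were higher for 7 of 11 (0.02, 0.917). Wnt-beta-catenin targets were higher for 4 of 7 with a median of 0.12, but a mean of -0.21 and a camera direction downwards (0.820), because Lgr5, at 0.421 ± 0.143 and 0.0925 ± 0.0326 CPM, had a log2 difference of -2.15, and it was the only member to pass when adjusted over the list alone. Without CaSRwt replicate 2 the median of this list was -0.11. The insulin-like growth factor axis was higher for 5 of 7 (0.01, 0.240), with Igfbp7 at 0.32 and Igfbp6 at 0.14.

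The other stress, immune and metabolic lists did not pass camera with all 6 libraries. Replication-dependent histones were called by the fry test for change in either direction (adjusted p = 0.00369). NF-kappaB and chemokine genes were higher for 11 of 18 (median 0.02, camera adjusted p = 0.689), unfolded protein response genes for 8 of 22 (-0.02, 0.820) and heat shock genes for 6 of 13 (-0.01, 0.819). Amino acid response genes were higher for 13 of 18 (median 0.03, mean -0.01, camera upwards, 0.422). Targets of p53 were higher for 5 of 18 (-0.06, 0.214), and Trp53inp1, at -0.25, passed when adjusted over the list alone. Glycolysis and hypoxia genes were higher for 15 of 22 (0.03, 0.487), cholesterol synthesis genes for 17 of 22 (0.04, 0.490) and nuclear genes of oxidative phosphorylation for 20 of 28 (0.02, 0.523). Mitochondrially encoded genes were higher for 10 of 15 (median 0.01, mean -0.00, camera upwards, 0.542) and replication-dependent histones for 7 of 14 (median 0.04, mean -0.05, camera upwards, 0.993). With 1 library left out, mitochondrially encoded genes passed without CaSRwt replicate 1, nuclear genes of oxidative phosphorylation without CaSRmut replicate 1 and cholesterol synthesis genes without CaSRmut replicate 3. Of the lists in this and the previous paragraph, BMP targets, Wnt-beta-catenin targets and p53 targets were those with a member past the threshold when adjusted over the list alone.

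Lists of markers of other cell types did not pass. Osteocyte genes were higher for 2 of 5 members tested (median -0.02, mean 0.05, camera upwards, adjusted p = 0.993), genes of osteoblast-osteoclast coupling for 2 of 6 (median -0.04, mean -0.02, camera upwards, 0.993), chondrocyte genes for 2 of 7 (-0.08, 0.917) and adipocyte genes for 2 of 5 (-0.02, 0.917). Haematopoietic markers were higher for 2 of 5 (-0.03, 0.689) and endothelial markers for 3 of 7 (median -0.06, mean -0.19, 0.689). Among the endothelial markers, Vwf stood at 8.14 ± 0.523 and 6.63 ± 0.718 CPM and Esam at 0.920 ± 0.227 and 0.452 ± 0.220 CPM, with log2 differences of -0.29 and -1.01, and neither passed when adjusted over the list alone (0.121 for both in edgeR). The groups of Vwf did not overlap, nor did those of Sox9, Krt14, Tek, Pdpn (osteocyte list) and Csf1 (coupling list). Groups of 3 and 3 libraries separate fully with a probability of 0.1 when they do not differ. Some such markers would therefore be seen without any difference. Sox9, a transcription factor of chondrocytes, stood at 158 ± 5.51 and 171 ± 3.33 CPM, and Lyz2, a myeloid lysozyme, at 8.76 ± 0.707 and 7.76 ± 0.600 CPM. Too few members were tested for camera in the epithelial (1 of 3 higher, median -0.20), skeletal muscle (3 of 4, 0.02) and neural lists (2 of 3, 0.11). With 1 library left out, these medians ran from -0.224 to 0.324, from -0.023 to 0.217 and from 0.0194 to 0.279. The keratin gene Krt14 stood at 19.9 ± 1.90 and 16.0 ± 2.13 CPM and passed when adjusted over the epithelial list alone (log2 difference -0.31).

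The make-up of the libraries was similar in the groups. Mitochondrially encoded genes took 2.78% ± 0.177 of counts in CaSRwt and 2.79% ± 0.141 in CaSRmut (SD, n = 3 each, exact permutation p = 0.9). Ribosomal protein genes took 4.11% ± 0.0808 and 4.24% ± 0.178 (exact permutation p = 0.4). The 10 most abundant genes, led by Casr, mt-Co1, Fn1 and Eef1a1, took 6.52% ± 0.218 and 6.38% ± 0.298 (exact permutation p = 0.6). Protein-coding genes took 97.7% ± 0.0340 and 97.8% ± 0.0746, the 1 share compared here whose groups did not overlap (exact permutation p = 0.1, the smallest that 3 libraries against 3 can give), and rRNA genes 0.244% ± 0.0157 and 0.228% ± 0.0103 (exact permutation p = 0.2). The first principal component of log2 CPM held 25.4% of the variance and set CaSRmut replicate 1 apart (42.1). On it the other CaSRmut libraries lay at 1.51 and -5.49 and the CaSRwt libraries at -9.09, -18.8 and -10.2, so the groups did not overlap, although most of its range lay between CaSRmut replicate 1 and the other 5 libraries.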

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

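The count of genes past the threshold was 1, and became 33 with no filter (17 higher, 16 lower), 2 with DESeq2 (H3f3c and Ly6e), 40 with the replicate block and 44 with the replicate block and length correction; limma-voom, each of the 3 FPKM settings and protein-coding genes only gave 0. The fit with no filter drew its variance estimates also on genes that the main filter removes. Leaving out each library gave 0 to 11, with 0 without CaSRwt replicate 2 and without CaSRmut replicate 2. The count past 2-fold as well was 1, and became 8 with no filter, 4 with the replicate block (Gm5786, H3f3c, Gsta1 and Gm14444, named after their values were seen), 5 with the replicate block and length correction (these and Gm14632), 0 with limma-voom and in the 3 FPKM settings, and 0 to 2 with a library left out. Of the other named genes, Spp1 (adjusted p = 0.00154), Cxcl10, Ly6e, Dhx58, Filip1l, Id3, Eid3, Gsta4, Slc35f1 and Rragd passed with the replicate block as well, and Slpi with the length correction added (0.0417). Among list members named above, Sparc, Col3a1, Bgn, Timp2, Trp53inp1, Atoh8 and Gclm also passed with the replicate block, and Col1a2 with the length correction added. The log2 fold change of Casr was -0.19 both with the replicate block (adjusted p = 0.000558) and with the replicate block and length correction (0.000248); over the other alternatives its adjusted p was above the threshold, and with a library left out it ran from -0.26 (without CaSRmut replicate 1) to -0.10 (without CaSRmut replicate 3). Deviations from the group means correlated between libraries of the same number at 0.0268, 0.0372 and 0.0657 for replicates 1, 2 and 3 over all genes tested, at 0.0587, -0.0037 and 0.211 over genes of at least 10 CPM, and at 0.0911, 0.216 and 0.398 over genes of at least 100 CPM. The rule set for pairing, over 0.1 for every number, was met at none of these levels, so the numbers were not taken as pairs. CaSRwt replicate 1 correlated best with CaSRmut replicate 2 at each level (0.236 at 100 CPM), and CaSRwt replicate 3 with its own number, a hint from the data and not the design that some libraries share a source of variation. The block left 6 lists called. The count of lists, 6, became 0 with an estimated correlation, 0 with fry and 2 to 7 with a library left out. For 15 named genes, 272 of 312 alternatives kept direction and side of the threshold, 34 gained a call, 6 lost one (H3f3c each time, adjusted p 0.137 to 0.864) and 0 reversed. For the 6 lists called and the osteoblast list, 57 of 84 kept both, 25 lost the call, 2 gained it and 0 reversed. The shares of mitochondrially encoded, ribosomal protein and the 10 most abundant genes moved by less than 1 SD, and other shares were run under no alternative. The cause of these differences was not tested. Genes near 1 CPM had wide intervals at this depth.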

Other observations

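The tests of a difference in Casr transcript, of reads carried over from H3f3a and of the variation of pseudogenes were chosen after the values had been seen. The other kinds of test in this part were chosen before. The interferon list tested below is the one with the smallest camera p in these same libraries, so its tests concern a pattern picked from the data. The genes named in this and the next paragraph were picked after their levels were seen. Interferon-induced genes were abundant in both groups: Oas3 stood at 918 CPM in CaSRwt and 953 CPM in CaSRmut, Irf7 at 445 and 449 CPM, Ifit1 at 315 and 344 CPM and Ifnb1, the gene of interferon beta, at 7.65 and 7.06 CPM. No untransfected culture was analysed here, so it is not known whether these levels precede transfection.

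Several genes of the osteoblast list had 0 counts in all 6 libraries. They were 7 of the 25 listed: Ibsp, Dlx5, Msx2, Postn, Bmp2, Bmp4 and Enpp1. Of 11 genes of osteoblast-osteoclast coupling, Tnfrsf11b, Wnt5a and Cxcl12 had 0 counts. A count of 0 allows up to 0.0774 to 0.0878 CPM per library. The cells were taken to be MC3T3-E1, an osteoblast line, per the labels. These zeros and the low counts of Sp7, Alpl and Bglap leave that identity in doubt, although Runx2, Col1a1 and Spp1 were well expressed. The identity was not tested here. Il1rl1, the gene of the interleukin 33 receptor, was abundant at 2191 and 2234 CPM. Gapdh, often used as a reference gene, had 855, 4111 and 971 counts in CaSRwt and 1031, 1001 and 3189 in CaSRmut, a range of 4.56-fold in CPM that did not follow the groups, while Actb stood at 1455 ± 43.8 and 1514 ± 50.2 CPM (SD, n = 3 each). Whether reads of Gapdh also match other genes was not examined, so this range need not be one of its transcript.

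Splits of the 6 libraries into 3 and 3 give 10 arrangements, too few for a share under 0.05, so they decide nothing about chance. For the count of genes past the threshold, 9 of 10 splits gave at least as many as the real value of 1, and the highest other split gave 38. That split sets CaSRwt replicate 1 and CaSRmut replicates 1 and 2 against the rest and had 1602 genes at an unadjusted p under 0.05, against 911 for the real one. This may reflect a structure among the libraries that does not follow the plasmids. The split was picked as the highest, so its count is no test of such a structure. For genes past 2-fold as well, 9 of 10 splits gave at least the real value of 1, with 2 as the highest other. For lists called by camera, 2 of 10 gave at least the real value of 6, with 7 as the highest other.

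H3f3c was the gene past the threshold. In its transcript, 267 of 362 windows of 50 bases (73.8%) occur without mismatch in transcripts of other genes, 245 of them in H3f3a, which makes its count uncertain but is the same in both groups. H3f3a had a log2 difference of 0.04, and its 95% interval ended at 0.143, below the 1.20 at which that of H3f3c began, which argues against a change in H3f3a carried over by a constant share of its reads. Greater variation of pseudogenes fits as a class, since the median within-group SD of log2 CPM was 0.379 over 1053 processed pseudogenes and 0.333 in 10000 matched sets of coding genes (percentile 100). Between the groups, 65 of these pseudogenes (6.17%) had an unadjusted p under 0.05, against a median of 4.65% in matched sets (percentile 99.54). The within-group SD of H3f3c itself, 0.327, was not unusual (percentile 65.7 of 469 coding genes of like abundance). Whether greater variation of pseudogenes accounts for H3f3c stays open, as do a share of H3f3a reads that varies between libraries and an effect of the mutant receptor, both untested.

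The interferon list was higher in CaSRmut by a mean of 0.0851 on the log2 scale, and 2 of the 10 splits gave a mean at least as far from 0, with 0.0879 as the highest other, which is too few splits to decide on chance. A single library does not carry the shift, since the lowest median over the 6 fits that left out 1 library was 0.0596 against 0.0885 with all of them. More plasmid transcript in CaSRmut is a possible explanation for an interferon response to transfected nucleic acid. It would need more Casr in CaSRmut, while the log2 fold change was -0.18 (95% interval -0.42 to 0.0541) and negative in every alternative, but the interval included a slight excess, so this cannot be told from these libraries, and plasmid DNA itself was not measured. A difference in signalling by the mutant receptor also stays open as a hypothesis and was not tested separately.

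A further hypothesis was that the cultures of the groups differ in the copy number of whole chromosomes, as cell lines may drift. The median log2 fold change of the genes of a chromosome (mean CPM of at least 10) lay farthest from 0 for chromosome 15, at 0.0207, well within the 0.1 set beforehand, so these data argue against a gain or loss of a whole chromosome in most cells of 1 group.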
